A study of Sus scrofa with 12 samples.

How the data were processed

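The data were 12 sections of pig heart, each 5 µm thick and placed on a 10x Visium slide, an array whose spots carry barcoded primers that capture poly-A RNA from the tissue above them. Per the labels, the hearts were taken at week 1, week 4 or week 12 and were sham hearts, hearts that received medium as a control, or hearts that received cells. The cells were human cardiovascular progenitors made from H1, an established human embryonic stem cell line, by 11 days of differentiation on the laminins LN521 and LN221, and they were transplanted into infarcted hearts. The labels do not say whether the sham and medium hearts were infarcted. Each week held 1 sham section, 1 medium section and 2 sections with cells, which the labels call biological replicates. Independence of the replicates is as labelled.

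The deposited files hold counts of unique molecular identifiers (UMIs) per gene and spot, made by the authors with Space Ranger, per the submitters' processing notes. The notes name the human build GRCh38, and the Space Ranger version is not given in the sources used here. The deposited feature list joins 20618 human genes and 21303 pig genes, and its identifiers separate the species. The files name 14874 of the pig genes, 654 more were named from an Ensembl name table, and 5775 stayed unnamed and were tested by identifier. The matrices list 37770 spots. Spot coordinates were not used here, so no position within a section is given. A spot is a small region that can hold several cells of both species, and no cell types were assigned to spots.

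Counts were summed per section with Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1), and figures were drawn with matplotlib 3.10.9. Sections held 8649086 to 25784956 UMIs. The human share of a section is its UMIs on human genes over all its UMIs, with an exact Clopper-Pearson 95% interval. All such intervals cover counting error only. A graft spot had at least 500 UMIs and a human share above 1.51%, the level that 0.1% of the 17746 such spots of sham and medium sections exceeded. A graft-free spot had a share at or below 0.560%, their 95th percentile. These rules, the comparisons, the tests and the 39 gene lists were fixed before the data were examined.

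Human genes were tested on human UMIs summed over the graft spots of the 6 sections with cells. A human gene entered when its share of all UMIs in graft spots was at least 5 times its share in sham and medium spots, so that genes with a high background in those spots stayed out, and 15903 of 16029 detected genes passed. Host genes were tested on pig UMIs summed over all spots of each section in an additive model of week and treatment, so that weeks stand as replicates of a treatment and treatments as replicates of a week. Cells and medium were also compared within each week, where the spread came from the 3 pairs of sections with cells and the lone medium section was assumed to vary like them. Graft and graft-free spots of a section were compared with the section as a block. Only the 2 sections of week 1 held at least 20 spots of each class. A second comparison, chosen after seeing the data, set human-rich spots (at least 20% human UMIs) against human-poor spots (under 5%) of all 6 sections with cells.

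Each count test was edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM normalization, glmQLFit and glmQLFTest), with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p values of genes are from this test unless another is named. Levels are CPM, counts scaled by edgeR to TMM-adjusted totals, of the pig counts for pig genes and of the human counts of graft spots for human genes, as mean ± SD over sections. Log2 fold changes carry their standard error (SE). TMM holds the bulk of genes level, so a change is relative to the other genes of the same species. Scaling by total counts alone shifted the median log2 fold change of all genes by 0.36 for cells against medium, 0.43 for medium against sham, 0.80 for cells against sham, 0.47 for week 12 and 0.32 for week 4 against week 1, 0.75 for graft against graft-free and 0.69 for human-rich against human-poor spots. In human genes the shift was -0.086 for week 4 against week 1, -0.37 for week 12 against week 1 and -0.28 for week 12 against week 4. Where that scaling moved the share of higher genes among those called by over 10 points, its split stands beside the first.

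Gene lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, and again with the correlation estimated from the data. Over the comparisons tested here no list passed with an estimated correlation. The limma test fry was run beside it. Counts of list members that passed are given over all genes and adjusted over the list alone. A gene with no UMI in 1 of the groups has a fold set against 3 counts over that group, written as at least that fold, which takes the other group's count as measured. Beside it stands the lower limit of the 95% counting interval of the ratio, which includes the error of that count. A gene with 1 to 3 UMIs there has a ratio with its counting interval.

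The genes described were the 10 with the largest change each way among those with an adjusted p under 0.05, an average log2 CPM of at least 4 and a symbol, up to 4 members of each list described, and MDK with its receptors in every comparison. A selection of these is printed, and one that is withheld is not reported here. The tests were tried on simulated counts with 200 changed genes per comparison. At a 4-fold change the share of changed genes recovered was 89.2% for cells against medium, 80.0% for medium against sham, 84.8% for cells against sham, 87.7% for week 12 and 86.2% for week 4 against week 1, 95.2% for human-rich against human-poor spots, 94.0% for graft against graft-free spots, 60.3% for human genes at week 12 against week 1 and 56.9% at week 4 against week 1. Within weeks it was 43.8%, 53.2% and 50.0% at weeks 1, 4 and 12, so smaller changes there were mostly out of reach, and for the change of the human-rich effect from week 1 to week 12 it was 25.4%. Among simulated calls of edgeR the false share was 21.8% for human genes at week 12 against week 4, 11.1% at week 4 against week 1 and 13.8% for cells against medium within week 4, above the 5% aimed at, and at most 9.28% in the other comparisons. For cells against medium over all weeks it was 2.61% with edgeR and 13.8% with DESeq2.

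Alternatives were DESeq2 1.42.0, total-count scaling, no filter on low counts, other spot classes and thresholds, muscle-rich or muscle-poor spots alone (at or above, or below, the median share of pig UMIs on contractile genes), 1 mean per group, leaving out mitochondrial and ribosomal genes, and leaving out each section. Replicates of a group differed by far more than sampling noise, with a chi-square per degree of freedom of 92.2, 58.1 and 110 for the pairs with cells at weeks 1, 4 and 12. Nothing in the labels ties replicate 1 of a week to replicate 1 of another. The labels give no library batch, and a batch that followed the weeks would not be separable from them. Near-identical gene copies and pig genes that can take up human reads are uncertain in counts made against both species, and 10910 pig genes had a human gene of the same symbol with more UMIs in human-rich spots.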

Results

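Pig hearts were sampled 1, 4 and 12 weeks after they received human cardiovascular progenitors derived from the H1 stem cell line, medium alone, or a sham operation, and 12 sections were profiled on a spatial RNA array. Each week had 1 sham section, 1 medium section and 2 sections with cells. The cells went into infarcted hearts, and the labels do not say whether the sham and medium hearts were infarcted. At week 1 the sham, the medium and the pair with cells held 19735449, 11237287, 23740960 and 13259200 UMIs. At week 4 they held 25784956, 13246063, 24386436 and 17859559, and at week 12 they held 8649086, 12303579, 11467136 and 17786845. Pig UMIs averaged 16812542 ± 5617013 a section at week 1, 17687651 ± 6672260 at week 4 and 7886726 ± 3612322 at week 12 (SD, n = 4 each), so that host genes rested on the fewest counts at week 12. The mitochondrial share of pig UMIs was 41.0% ± 9.16 in sham, 32.8% ± 13.1 in medium (n = 3 each) and 21.7% ± 9.24 in cells sections (n = 6). Contractile genes took 7.54% ± 1.42, 7.58% ± 2.98 and 5.97% ± 3.28 of pig UMIs in the same groups.

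Human RNA was found in all 6 sections with cells and took a larger share of them at the later weeks. The human share of UMIs averaged 1.71% ± 0.68 at week 1, 26.4% ± 14.5 at week 4 and 59.1% ± 29.4 at week 12 (SD, n = 2 each). The week 1 sections held 2.19% (95% CI 2.18 to 2.19) and 1.23% (1.22 to 1.24), the week 4 sections 16.1% (16.1 to 16.1) and 36.7% (36.7 to 36.7), and the week 12 sections 38.3% (38.3 to 38.4) and 79.9% (79.9 to 80.0). The 6 sections without cells held 0.0826% to 0.228%, the background level of this measure, whose source was not tested. The share was 84.2 times higher in sections with cells by geometric mean (two-sided exact permutation test, p = 0.00216, the smallest that 924 splits can give). Leaving out week 12 cells replicate 2 gave 58.6 times, and leaving out week 1 cells replicate 2 gave 135 times. The weeks themselves, with 2 sections each, were not tested.

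Graft spots, regions whose human share passed 1.51%, made up 37.6% (36.0 to 39.3) and 9.61% (8.49 to 10.8) of the spots of the week 1 sections. They made up 71.3% (69.8 to 72.7) and 99.97% (99.8 to 100) at week 4, and 89.2% (88.1 to 90.3) and 99.8% (99.6 to 99.95) at week 12. Sections without cells had 0% to 0.334%. The difference between sections with and without cells was 67.8 points (two-sided exact permutation test, p = 0.00216), and it was 30.0 points for spots that were at least 20% human. Few or no spots at weeks 4 and 12 lay at the graft-free level, with 3 and 0 graft-free spots in the sections of either week against 810 and 1919 at week 1. The threshold comes from sections without human cells, so a graft spot need not hold human cells, and spread of human RNA between spots was not tested. With the highest sham or medium spot (5.39%) as threshold, graft spots made up 32.8% and 70.6% at week 4. At week 12 they made up 51.7% and 95.5%.

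**Figure D1:**
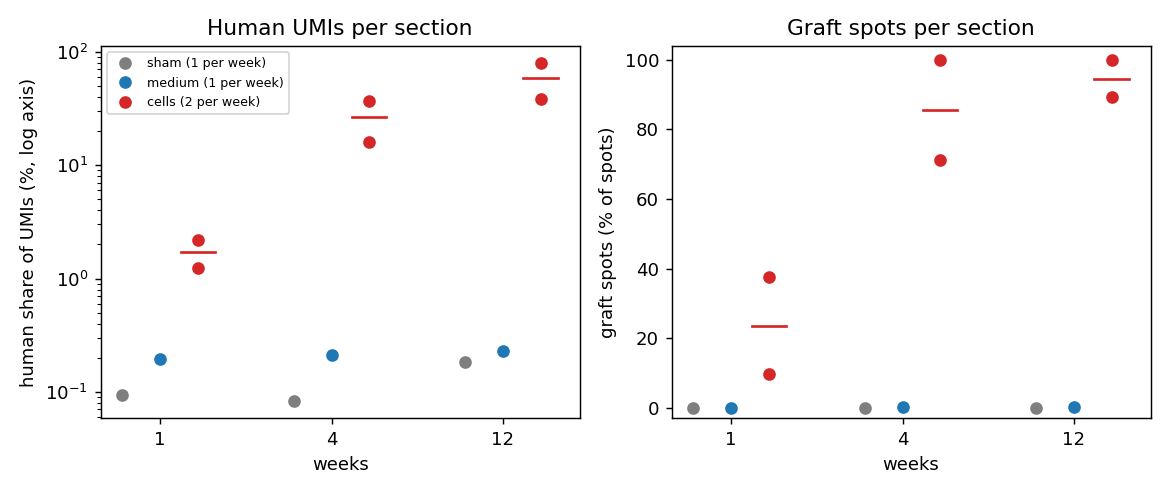
Human share of UMIs (left, percent, log axis) and graft spots (right, percent of spots) in each of the 12 sections by week, for sham, medium and cells, each point being 1 section and the bar the mean of the 2 sections with cells. The human shares of the sections with cells lie between 1.23% and 79.9%, all above the highest section without cells at 0.228%.

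Midkine (MDK, ENSG00000110492), a secreted growth factor named in the title of the series as a regulator of new vessel growth, fell in the human cells over the weeks. Human MDK stood at 2720 ± 732 CPM at week 1, 1070 ± 71.2 at week 4 and 263 ± 95.4 at week 12 (SD, n = 2 each). It was 2.55-fold lower at week 4 than at week 1 (log2 -1.35 ± 0.30 SE, adjusted p = 0.0110) and 10.3-fold lower at week 12 than at week 1 (log2 -3.37 ± 0.32, adjusted p = 3.92e-05). From week 4 to week 12 it was 4.05-fold lower (log2 -2.02 ± 0.30, adjusted p = 0.00142). The 2 calls at week 12 held under every alternative run. No alternative separates the weeks from a library batch that followed them, here or in the other contrasts of human genes between weeks. The call at week 4 ended without week 1 cells replicate 1 (log2 -1.03, adjusted p = 0.0803), without week 4 cells replicate 1 (-1.26, adjusted p = 0.12) and without week 4 cells replicate 2 (-1.41, adjusted p = 0.0838). Midkine receptors SDC4, a syndecan, and GPC2, a glypican, were 3.17-fold and 8.11-fold lower at week 4 than at week 1, and 2.81-fold and 11.2-fold lower at week 12. The receptor LRP1 was 2.41-fold lower at week 4 than at week 1 and 2.42-fold higher at week 12 than at week 4. Of 11 midkine receptor genes 3 fell at week 4 and 3 at week 12 against week 1 (3 and 3 adjusted over the list alone). Camera gave adjusted p = 0.0108 and 0.0309, and adjusted p = 0.157 and 0.234 with an estimated correlation. The week 4 call of GPC2 ended without any of the same 3 sections and its week 12 call without week 1 cells replicate 1, and the week 4 call of LRP1 ended without replicate 1 of week 1 or of week 4.

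Genes of mature heart muscle rose in the human cells. COX6A2, the muscle form of a cytochrome c oxidase subunit, was 7.17-fold higher at week 4 and 15.3-fold higher at week 12 than at week 1 (2214 ± 36.8 against 136 ± 56.3 CPM, n = 2 each). MYOM2, a structural protein of the sarcomere M-band, was 31.2-fold higher at week 12 (log2 4.96 ± 0.40 SE, adjusted p = 1.31e-05), the mitochondrial creatine kinase CKMT2 was 7.27-fold higher, and the ventricular myosin light chain MYL2 was 8.05-fold higher and reached 23790 ± 364 CPM. MYH6, a myosin heavy chain of atrial and early heart muscle, went the other way and was 11.7-fold lower at week 4 and 7.6-fold lower at week 12. Among 16 mature cardiomyocyte genes 11 rose by week 4 and 14 by week 12 (13 and 16 adjusted over the list alone). Camera gave adjusted p = 9.14e-14 and 4.99e-20, and adjusted p = 0.0946 and 0.0845 with an estimated correlation. Of 16 contractile genes 9 rose and 1 fell by week 12 (9 and 1 adjusted over the list alone), among them TCAP, 4.94-fold higher, with camera adjusted p = 0.000329 and adjusted p = 0.428 with an estimated correlation. Fatty acid genes rose too: CPT1B, which carries fatty acids into mitochondria, was 7.07-fold higher at week 4 (log2 2.82 ± 0.36). The fatty acid transporter CD36, the lipase LPL and the kinase PDK4 had no UMI at week 1 and were at least 56.0-fold, 57.3-fold and 110.5-fold higher at week 12 (lower limits of the counting interval 45.5, 46.6 and 89.8). Of 17 fatty acid oxidation genes 8 rose and 1 fell at week 4, and 14 rose at week 12 (10 up and 1 down, and 15 up, adjusted over the list alone). Camera gave adjusted p = 2.73e-08 and 3.76e-14, and adjusted p = 0.0946 and 0.0845 with an estimated correlation. Oxidative phosphorylation had 11 of 18 genes higher at week 12 (11 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.49e-05, and adjusted p = 0.234 with an estimated correlation). Glycolysis went down at week 12, with ENO1 5.47-fold, LDHA 3.53-fold and the glucose transporter SLC2A1 4.24-fold lower. Of its 14 genes 8 fell (10 adjusted over the list alone; camera adjusted p = 1.04e-07, and adjusted p = 0.292 with an estimated correlation).

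Endoderm, cartilage and endothelial genes fell in the human cells after week 1, while fibroblast genes rose by week 12. AFP, the fetal liver protein alpha-fetoprotein, had no UMI at week 4 and was at least 3059-fold lower there (lower limit of the counting interval 2478). The liver genes VTN, AMBP and APOA1 were 196-fold, 109-fold and 35.3-fold lower at week 4, and COL2A1, the collagen of cartilage, was 41.4-fold lower at week 4 and 1159-fold lower at week 12 (log2 -10.18 ± 0.30 SE, adjusted p = 9.48e-09). Of 12 endoderm and epithelium genes 11 fell at week 4 and 11 at week 12 (11 and 11 adjusted over the list alone). Camera gave adjusted p = 2.93e-25 and 6.77e-26, and adjusted p = 0.0946 and 0.0901 with an estimated correlation. Of 6 cartilage and bone genes 3 fell and 1 rose at either week (5 fell and 1 rose adjusted over the list alone). By camera adjusted p was 3.82e-06 and 3.74e-06, and adjusted p = 0.149 and 0.0958 with an estimated correlation. Human endothelial genes fell as well: EGFL7 went from 127 ± 6.60 CPM at week 1 to 14.0 ± 2.45 at week 4 and 4.90 ± 2.70 at week 12 (n = 2 each), and CLDN5, a tight junction protein, was 45.4-fold and 98.8-fold lower. KDR, the main VEGF receptor, was 26.6-fold lower at week 4 and at least 131-fold lower at week 12 (14 UMIs against 0, lower limit of the counting interval 93.2). Of 7 endothelial genes 5 fell at either week (5 and 5 adjusted over the list alone). Camera gave adjusted p = 2.08e-08 and 2.35e-07, and adjusted p = 0.0946 and 0.0901 with an estimated correlation. Dividing-cell genes were higher at week 4 than at week 1, with CDK1 3.84-fold and HMGB2 2.55-fold higher, and 7 of 19 cell cycle genes rose (11 adjusted over the list alone; camera adjusted p = 0.000301, and adjusted p = 0.446 with an estimated correlation). The vessel growth factors VEGFA and FGF1 were 2.60-fold and 10.6-fold higher at week 4, but their list went both ways. Of 17 angiogenic ligand genes 2 rose and 4 fell at week 4, and 2 rose and 5 fell at week 12 (2 up and 6 down at either week adjusted over the list alone). By camera adjusted p was 0.323 and 0.0445, lower, and adjusted p = 0.657 and 0.234 with an estimated correlation. Of 11 vessel growth genes 6 fell at either week (6 and 6 adjusted over the list alone). By camera adjusted p was 4.14e-07 and 7.23e-06, and adjusted p = 0.148 and 0.0901 with an estimated correlation. Of 11 fibroblast genes 2 rose at week 4 and 5 at week 12 (2 up and 2 down, and 6 up, adjusted over the list alone). By camera adjusted p was 0.269 and 0.00110, and adjusted p = 0.767 and 0.428 with an estimated correlation. The list median was at log2 1.51 and 3.10, and at 0.49 and 1.88 with genes near 0 UMIs at their bound. Of 8 activated fibroblast genes 2 fell at week 4, and 2 rose and 1 fell at week 12 (2 down, and 3 up and 2 down, adjusted over the list alone). Their medians with such genes at their bound were 0.09 and 1.25, while camera pointed lower (adjusted p = 0.123 and 0.892, and adjusted p = 0.660 and 0.942 with an estimated correlation). Of 12139 human genes, 1007 were higher and 964 lower at week 4 than at week 1, and 1593 were higher and 1369 lower at week 12. Scaled by total counts, 865 were higher and 1205 lower at week 4, and 929 higher and 2260 lower at week 12. Leaving out week 1 cells replicate 1 gave 544 genes at week 4 and 1154 at week 12 and ended the week 4 calls of CLDN5, CDK1 and VEGFA, and leaving out week 4 cells replicate 1 or 2 gave 852 and 979 at week 4. Spots at least 20% human gave 1150 at week 4. With every section thinned to 126649 human UMIs 469 passed at week 4 and 724 at week 12, without HMGB2 at week 4 and SLC2A1 at week 12.

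**Figure D2:**
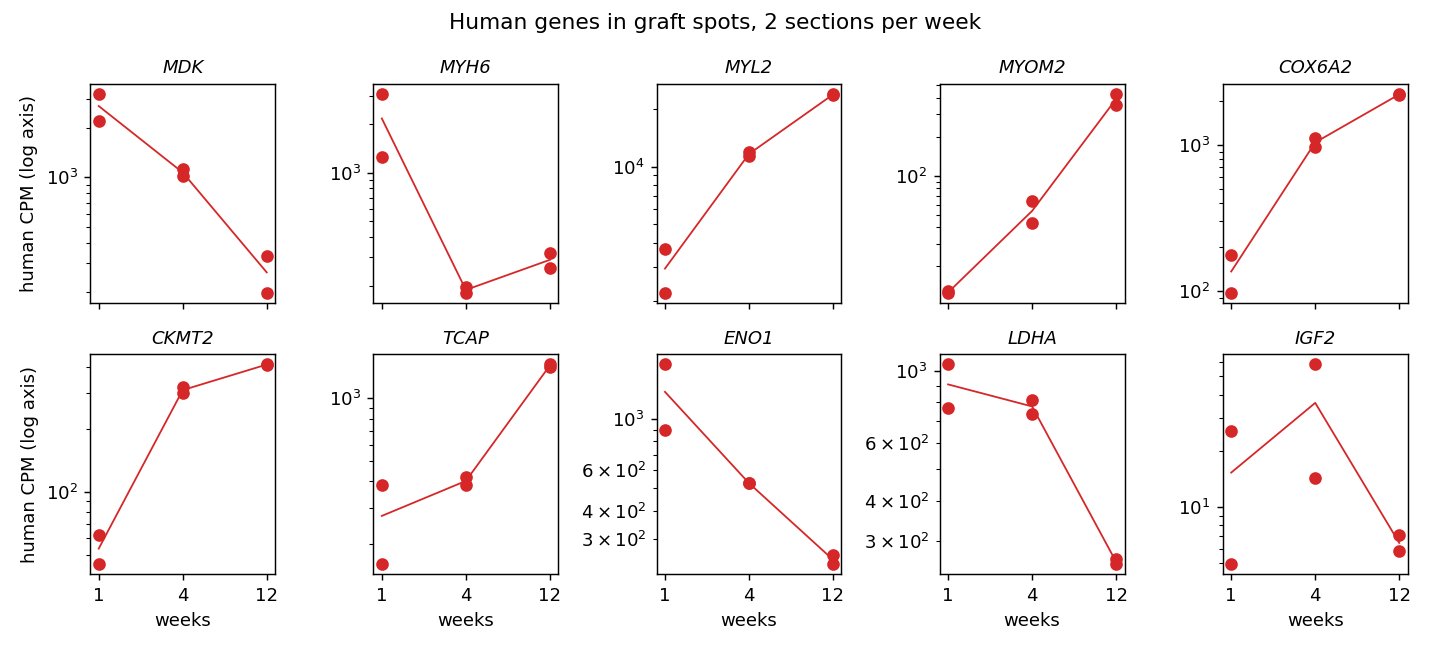
Levels of 10 human genes (CPM of the human counts of graft spots, log axis) in the 6 sections with cells by week, each point 1 section and the line joining the means of 2. MDK goes from a mean of 2720 at week 1 to 263 at week 12, while MYL2 goes up to 23790.

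Between weeks 4 and 12 the human cells gained further muscle and fatty acid genes. PDK4, LPL and CD36 were 5.38-fold, 4.68-fold and 3.97-fold higher at week 12 than at week 4, MYOM2 was 7.24-fold higher (392 ± 55.0 against 53.7 ± 15.2 CPM, n = 2 each), and the peroxidase-like PXDNL was 69.0-fold higher (log2 6.11 ± 0.29 SE, adjusted p = 1.71e-06). RPL3L, a ribosomal protein of striated muscle, had 1 UMI at week 4 and a ratio of 962 (counting interval 172 to 38013). The early genes HMGA2 and CLDN6 were 19.7-fold and 141-fold lower. Of 16 mature cardiomyocyte genes 8 rose (8 adjusted over the list alone), and of 17 fatty acid oxidation genes 7 rose (7 adjusted over the list alone). Both had camera adjusted p = 9.03e-09, and adjusted p = 0.489 with an estimated correlation. Glycolysis fell again, with 6 of 14 genes lower (7 adjusted over the list alone; camera adjusted p = 3.67e-05, and adjusted p = 0.489 with an estimated correlation). VEGFA was 2.33-fold lower and IGF2 5.54-fold lower. Cell cycle genes fell in 7 of 19 (9 adjusted over the list alone; camera adjusted p = 0.000243, and adjusted p = 0.489 with an estimated correlation), with CCNB1 2.25-fold lower. Human matrix genes were higher at week 12: SPARC 4.06-fold, TIMP1 2.57-fold and COL1A1 4.41-fold (1095 ± 771 against 248 ± 110 CPM). Extracellular matrix had 12 of 19 genes higher (17 adjusted over the list alone; camera adjusted p = 0.000132, and adjusted p = 0.530 with an estimated correlation). Antigen presentation had 6 of 10 higher (9 adjusted over the list alone), led by HLA-B at 2.04-fold, with camera adjusted p = 0.000438 and adjusted p = 0.489 with an estimated correlation. In all 1148 genes were higher and 931 lower, against 689 and 2665 when scaled by total counts. Leaving out week 4 cells replicate 1 or 2 gave 397 and 430 genes and ended the calls of TIMP1, COL1A1 and HLA-B, in the first case also those of SPARC, VEGFA and IGF2, and with every section thinned to 126649 human UMIs 15 genes passed, without LPL, CD36, HMGA2, CLDN6, VEGFA or the matrix and HLA genes named.

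In the host tissue at week 1, graft spots had more matrix and less muscle RNA than graft-free spots. In graft spots pig TNC, a matrix protein of injured tissue, was 6.82-fold higher than in graft-free spots of the same sections, THBS2 6.42-fold, SFRP2, a secreted Wnt modulator, 9.66-fold, and APOE, a lipid carrier that macrophages make, 11.7-fold (1143 ± 671 against 92.6 ± 37.4 CPM, n = 2 sections). The growth factor PTN, the closest relative of midkine, was 6.55-fold higher, and pig MDK (ENSSSCG00000013260) was 2.90-fold higher (log2 1.53 ± 0.26 SE, adjusted p = 8.38e-08). In the human-rich spots of replicates 1 and 2, human MDK had 537 and 235 UMIs against 57 and 99 for pig MDK. Human reads counted on the pig gene are thus not excluded. Pig TNNI3, cardiac troponin I, was 3.95-fold lower, MYOM2 4.48-fold and the mitochondrial gene ND1 5.54-fold lower. All 21 extracellular matrix genes rose (21 adjusted over the list alone; camera adjusted p = 4.5e-20), 12 of 13 macrophage genes rose (12 adjusted over the list alone; camera adjusted p = 1.4e-06), and all 14 contractile genes fell (14 adjusted over the list alone; camera adjusted p = 1.15e-09), each with adjusted p = 0.547 with an estimated correlation. In all 2064 of 10801 genes were higher and 1791 lower, against 5615 and 249 when scaled by total counts, 601 and 722 by DESeq2, and 970 and 1481 with graft spots at least 20% human. These p values rest on 2 sections and 1 residual degree of freedom per gene, with a spread borrowed across genes. Spots were classed by their human share, so a spot with less pig RNA passed on fewer human UMIs. Of the graft-free spots, 794 of 810 were muscle-rich in week 1 cells replicate 1 and 772 of 1919 in replicate 2. Part of the muscle and matrix difference can thus come from the classing. Graft-free muscle-poor spots numbered 16 in week 1 cells replicate 1, too few to compare.

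Across all 6 sections with cells, human-rich regions differed from human-poor regions of the same section in immune and muscle genes. Pig CCL5, a T cell chemokine, was 6.73-fold higher (231 ± 93.5 against 33.3 ± 11.5 CPM, n = 6), the T cell gene CD2 7.28-fold, the interferon-induced chemokine CXCL11 22.5-fold, the macrophage genes AIF1 and CD68 5.58-fold and 5.05-fold, and SLA-DRA, a pig class II antigen presentation gene, 4.20-fold (log2 2.07 ± 0.25 SE, adjusted p = 6.84e-07), each in 6 of 6 sections. JCHAIN, made by plasma cells, was 10.3-fold higher in 5 of 6. All 19 interferon response genes rose (19 adjusted over the list alone; camera adjusted p = 4.34e-11) and 13 of 14 macrophage genes rose (13 adjusted over the list alone; camera adjusted p = 1.14e-11), and both had adjusted p = 0.221 with an estimated correlation. Of 11 T and NK cell genes 10 rose (10 adjusted over the list alone; camera adjusted p = 7.55e-07, and adjusted p = 0.221 with an estimated correlation). All 12 antigen presentation genes rose (12 adjusted over the list alone; camera adjusted p = 2.87e-08, and adjusted p = 0.230 with an estimated correlation). All 14 contractile genes fell (14 adjusted over the list alone; camera adjusted p = 5.98e-19, and adjusted p = 0.221 with an estimated correlation), with the myosin light chain MYL3 at 303 ± 325 against 2765 ± 1921 CPM, 12.7-fold lower. All 16 oxidative phosphorylation genes fell (16 adjusted over the list alone; camera adjusted p = 9.35e-19, and adjusted p = 0.221 with an estimated correlation). Against human-poor regions that were also poor in muscle 12 of 19 interferon response, 9 of 13 macrophage, 4 of 10 T and NK cell and 10 of 12 antigen presentation genes passed.

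Pig MDK was 2.69-fold higher in human-rich than in human-poor regions (293 ± 163 against 101 ± 27.1 CPM, log2 1.43 ± 0.20 SE, adjusted p = 4.23e-06, higher in 6 of 6 sections). Human MDK UMIs in the same spots outnumbered pig MDK UMIs in every section, and a share of human reads counted on the pig gene is not excluded. The receptors SDC2, ITGA4, ITGA6, SDC1, SDC3 and NOTCH2 were 5.83-fold, 3.56-fold, 2.75-fold, 2.54-fold, 2.17-fold and 2.02-fold higher. PTPRB, counted here in the midkine receptor list, was 1.59-fold higher in 4 of 6 sections. NCL (log2 -0.16 ± 0.19, adjusted p = 0.530) and ITGB1 (log2 0.25 ± 0.19, adjusted p = 0.294) did not pass. With total-count scaling NCL was at 0.55 (adjusted p = 0.0249), a move close to the shift of the median of all genes under that scaling. Of 9 midkine receptor genes 7 rose (7 adjusted over the list alone; camera adjusted p = 0.00291, and adjusted p = 0.230 with an estimated correlation). Vessel growth genes rose in 14 of 17 (16 adjusted over the list alone; camera adjusted p = 0.000319, and adjusted p = 0.312 with an estimated correlation), among them NOTCH1 2.94-fold, PLVAP 2.88-fold and CD34 2.45-fold. Of 14 endothelial genes 5 rose (5 adjusted over the list alone; camera adjusted p = 0.192). In all 2716 of 11364 genes were higher and 2027 lower, against 7093 and 930 when scaled by total counts. Against human-poor regions that were also poor in muscle 756 genes passed, and MDK (log2 0.96 ± 0.29, adjusted p = 0.0567), PLVAP, CD34 and the receptors named other than SDC2 no longer passed. With genes open to human reads left out 1469 of 3286 passed, without PTPRB (log2 0.09, adjusted p = 0.783).

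**Figure D3:**
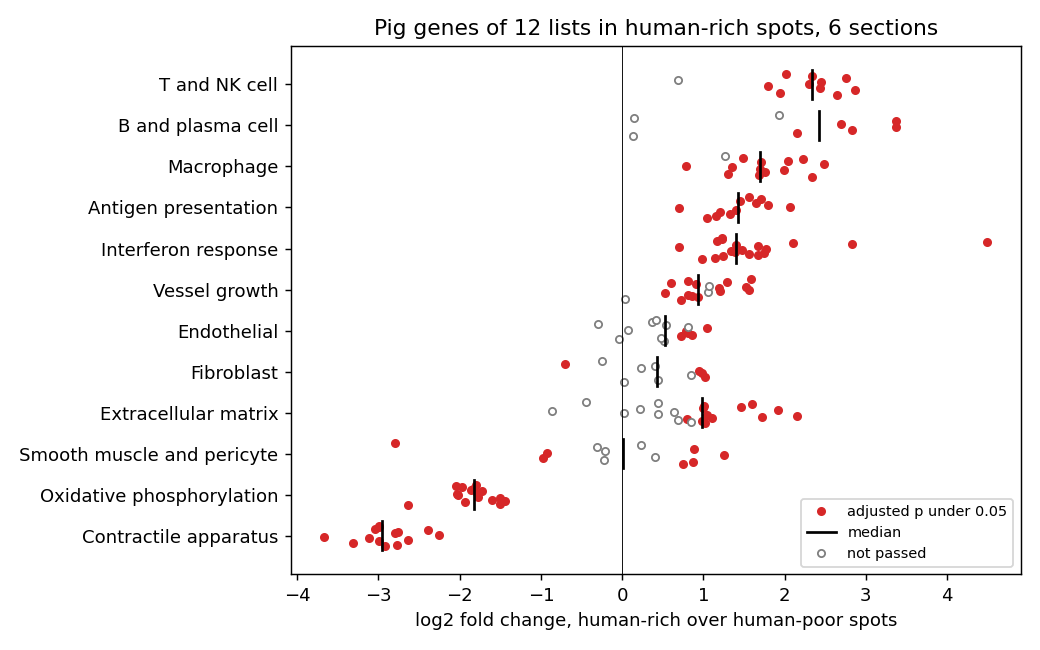
Log2 fold changes of pig genes in human-rich against human-poor spots for 12 gene lists, each point 1 gene, filled where its adjusted p was under 0.05 and open where not, and the bar the list median. Contractile and oxidative phosphorylation genes lie below 0, and all 19 interferon response genes lie above it.

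The difference between human-rich and human-poor regions itself changed with the week for vessel, matrix and muscle genes. Capillary genes had a higher effect at week 12 than at week 1: FABP4 by 3.12 ± 0.49 on the log2 scale (SE, adjusted p = 1.96e-07), the water channel AQP1 by 2.83 ± 0.51, the carbonic anhydrase CA4 by 3.58 ± 0.57 and KDR by 2.70 ± 0.60. These are differences of effects and do not give the sign of the effect within a week. The smallest classes held 28 human-rich spots, in week 1 cells replicate 2, and 96 human-poor spots, in week 12 cells replicate 2. Of 14 endothelial genes 5 had a higher effect at week 12 than at week 1 (9 adjusted over the list alone; camera adjusted p = 7.57e-12, and adjusted p = 0.235 with an estimated correlation), and 2 at week 4 than at week 1 (11 adjusted over the list alone; camera adjusted p = 3.21e-13, and adjusted p = 0.372 with an estimated correlation). Matrix genes had a lower effect at week 12, with TNC at -3.22 ± 0.47, COL1A1 at -2.64 ± 0.51 and CTHRC1 at -2.61 ± 0.50. Of 21 extracellular matrix genes 10 were lower (14 adjusted over the list alone; camera adjusted p = 4.82e-25, and adjusted p = 0.235 with an estimated correlation), and of 14 contractile genes 8 were lower, ACTC1 and MYBPC3 among them (12 adjusted over the list alone; camera adjusted p = 3.93e-17, and adjusted p = 0.235 with an estimated correlation). For pig MDK the effect differed by -0.46 ± 0.42 (week 4 minus week 1, adjusted p = 0.932) and -0.48 ± 0.44 (week 12 minus week 1, adjusted p = 0.795), which did not pass. Its direction turned without week 1 cells replicate 2 (0.21 and 0.20, adjusted p = 0.990 and 0.962), and it was -1.04 and -1.05 without week 1 cells replicate 1 (adjusted p = 0.740 and 0.630). On simulated counts the test of week 12 minus week 1 recovered 25.4% of 4-fold and 53% of 8-fold differences, so a smaller difference was mostly out of reach. In all 24 genes had a higher and 11 a lower effect at week 4, and 70 a higher and 117 a lower effect at week 12, on 2 sections a week, against totals of 12 and 119 by DESeq2. Without week 1 cells replicate 2 the week 4 total was 7, and the week 12 total was 87 or 103 without week 1 cells replicate 1 or 2 and 75 or 80 without week 12 cells replicate 1 or 2. In that order these ended the calls of ACTC1 and MYBPC3, of KDR, of CTHRC1 and ACTC1, and of COL1A1 and MYBPC3.

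Over whole sections, host genes with cells were compared with host genes after medium alone, the control without cells, and no single gene passed the test. Pig MDK stood at 109 ± 50.4 CPM in cells sections (n = 6) and 64.2 ± 19.9 in medium sections (n = 3), a 1.67-fold difference (log2 0.74 ± 0.29 SE, adjusted p = 0.486). The receptors SDC1 (log2 0.90 ± 0.27) and SDC2 (0.74 ± 0.26), the macrophage gene CD68 (1.36 ± 0.41), the T cell gene CD2 (1.55 ± 0.53) and JCHAIN (2.58 ± 0.77) also had adjusted p = 0.486. Week 12 cells replicate 2 stood apart from the other cells sections in MDK, CD68, CD2 and JCHAIN (204, 78.5, 40.1 and 252 CPM against at most 112, 30.1, 15.9 and 86.2). Without it their log2 fold changes were 0.55, 1.03, 1.18 and 2.25. As groups, immune genes lay higher with cells by camera: interferon response with 0 of 19 genes passing (0 adjusted over the list alone; camera adjusted p = 3.47e-08), antigen presentation with 0 of 12 (1 adjusted over the list alone; 1.15e-07), macrophage with 0 of 14 (0 adjusted over the list alone; 4.02e-06) and B and plasma cells with 0 of 7 (5 adjusted over the list alone; 5.7e-05). Mature cardiomyocyte genes lay lower, with 0 of 14 passing (0 adjusted over the list alone; camera adjusted p = 5.55e-05). For each of these 5 lists adjusted p = 0.555 with an estimated correlation. Without week 12 cells replicate 2 camera gave adjusted p = 3.00e-09, 7.91e-11, 2.89e-06, 6.56e-06 and 2.08e-05 in the same order, and adjusted p = 0.405 for each with an estimated correlation. Of 12421 genes edgeR called 0, with 1253 under an unadjusted p of 0.05, and DESeq2, whose calls in this comparison were 13.8% false on simulated counts, called 5 higher and 1 lower, RUNX2 (log2 1.72, adjusted p = 0.0324) among them. Within weeks edgeR called 0 of 12921 genes at week 1, 0 at week 4 and 0 at week 12, with 995, 124 and 1978 under an unadjusted p of 0.05 and 6, 2 and 80 by DESeq2. There were 184, 9 and 584 with no filter on low counts, and 472, 13 and 75 with human-rich spots left out. Pig MDK differed by 1.06 ± 0.48 at week 1 (adjusted p = 0.670), 0.22 ± 0.46 at week 4 (adjusted p = 1.00) and 0.93 ± 0.48 at week 12 (adjusted p = 0.369). Week 12 antigen presentation genes had 0 of 12 passing (9 adjusted over the list alone; camera adjusted p = 3.96e-08, and adjusted p = 0.645 with an estimated correlation). Without week 12 cells replicate 1, 2642 genes passed at week 12, and 29 passed without replicate 2. Each week has 1 medium section, assumed in all comparisons within a week to vary like the cells sections. Leaving out either replicate sets 1 cells section against it, with a spread taken from the other weeks. MDK was at log2 1.30 (adjusted p = 0.0320) in the first and 0.44 (adjusted p = 0.747) in the second. With the same sections left out, 231 and 237 passed at week 1 and 2 and 2 at week 4, and with human-rich spots left out MDK passed at week 1 (log2 1.00, adjusted p = 0.0415) and was at 0.34 (adjusted p = 1.00) over all weeks. With graft spots left out, week 4 cells replicate 2 and week 12 cells replicate 2 kept 1 and 4 spots, under 20, and were dropped. In the sections that remained MDK was at 0.00 over all weeks (adjusted p = 0.998) and at 0.84 within week 1 (adjusted p = 0.267). Within weeks 4 and 12, with 1 cells section against 1 medium section, MDK was at -0.62 and -0.52. Over all weeks it was at 0.38 in muscle-rich and 0.47 in muscle-poor spots (adjusted p = 0.770 and 0.819), and at 1.15 with total-count scaling (adjusted p = 0.353).

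Medium against sham showed matrix and activated fibroblast genes higher in medium sections (n = 3 each, 1 a week). Whether either group was infarcted is not labelled, so an effect of medium cannot be told apart from one of infarction. COMP, a cartilage matrix protein, was 96.6-fold higher, KERA, a small proteoglycan, 33.3-fold (log2 5.06 ± 0.43 SE, adjusted p = 0.000848), TNC 20.6-fold, PTN 16.4-fold (52.4 ± 4.94 against 3.68 ± 2.52 CPM) and COL1A1 4.49-fold (1336 ± 311 against 308 ± 59.8 CPM). CISH, a feedback inhibitor of cytokine signalling, was 3.22-fold lower. Of 21 extracellular matrix genes 13 rose (21 adjusted over the list alone; camera adjusted p = 2.7e-27, and adjusted p = 0.111 with an estimated correlation). Activated fibroblast genes rose in 7 of 10, THBS4 and FAP among them (9 adjusted over the list alone; camera adjusted p = 1.17e-13, and adjusted p = 0.111 with an estimated correlation). TGF-beta targets rose in 3 of 12 (6 adjusted over the list alone; camera adjusted p = 2.44e-09, and adjusted p = 0.0980 with an estimated correlation). Of 16 oxidative phosphorylation genes 0 passed (0 adjusted over the list alone; camera adjusted p = 9.11e-06, lower, and adjusted p = 0.636 with an estimated correlation). Pig MDK did not differ past the test (64.2 ± 19.9 against 60.7 ± 8.67 CPM, log2 0.02 ± 0.32, adjusted p = 0.986). Its sign varied with the setting, from -0.41 in muscle-rich spots (adjusted p = 0.281) to 0.44 with total-count scaling (adjusted p = 0.505). Its receptor SDC1 was 3.46-fold higher. In all 207 genes were higher and 6 lower, against 465 and 129 by DESeq2. The total was 462 with total-count scaling, 359 with no filter on low counts and 685 in muscle-rich spots. A model with 1 mean per group ended the calls of FAP, COL1A1 and SDC1. It was 2 without the week 4 sham and 6 in muscle-poor spots, which ended every call named here but that of KERA. It was 139 without the week 1 sham, 82 and 124 without week 1 cells replicate 1 or 2, 32 without the week 4 medium, 34 without the week 12 sham, 88 without the week 12 medium and 420 without week 12 cells replicate 2.

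Cells against sham showed higher matrix and macrophage genes and lower genes of oxidative phosphorylation and fatty acid oxidation (n = 6 against 3). The hearts with cells were infarcted and the sham hearts are not labelled for it, so these differences can hold an effect of infarction. APOE was 19.1-fold higher (221 ± 101 against 11.9 ± 8.28 CPM, log2 4.25 ± 0.60 SE, adjusted p = 0.00542), SFRP2 65.7-fold, PTN 19.6-fold, GPNMB, a macrophage gene, 8.05-fold and JCHAIN 11.2-fold. MYOM2 was 4.44-fold lower, the creatine kinase CKM 3.50-fold, ACAA2, an enzyme of fatty acid breakdown, 3.26-fold and SDHB, of the respiratory chain, 2.41-fold. Of 21 extracellular matrix genes 20 rose (21 adjusted over the list alone; camera adjusted p = 7.58e-18, and adjusted p = 0.278 with an estimated correlation), and of 14 macrophage genes 10 rose (13 adjusted over the list alone; camera adjusted p = 1.25e-06, and adjusted p = 0.395 with an estimated correlation). Of 7 B and plasma cell genes 4 rose, JCHAIN among them (4 adjusted over the list alone; camera adjusted p = 0.0261, and adjusted p = 0.395 with an estimated correlation). Oxidative phosphorylation fell in 13 of 16 (16 adjusted over the list alone; camera adjusted p = 9.7e-10, and adjusted p = 0.395 with an estimated correlation) and fatty acid oxidation in 7 of 17 (15 adjusted over the list alone; camera adjusted p = 4.65e-07, and adjusted p = 0.395 with an estimated correlation). Midkine receptors rose in 5 of 10 (5 adjusted over the list alone; camera adjusted p = 0.00258, and adjusted p = 0.362 with an estimated correlation), with SDC1 6.44-fold, SDC2 3.34-fold and NOTCH2 2.23-fold higher. Pig MDK was at log2 0.76 ± 0.29 (adjusted p = 0.0825) and passed with total-count scaling (1.59, adjusted p = 0.00884) and without week 4 cells replicate 1 (0.91, adjusted p = 0.0428). It was at -0.03 in muscle-rich spots (adjusted p = 0.972), 0.06 with graft spots left out (adjusted p = 0.971) and 0.39 with human-rich spots left out (adjusted p = 0.235). Without the week 12 sham it was at 0.49 (adjusted p = 0.329). In all 1306 genes were higher and 825 lower, against 6857 and 56 with total-count scaling and 1613 and 1716 by DESeq2. Muscle-rich spots gave 250 and 102. Muscle-poor spots gave 347 and 69, which ended the calls of CKM, ACAA2 and SDHB. Either class of spots ended that of NOTCH2. With human-rich spots left out 986 genes were higher and 808 lower, 1502 of them shared. With graft spots left out 6 genes passed. That setting also dropped week 4 cells replicate 2 and week 12 cells replicate 2, which kept 1 and 4 spots. The total was 30 without the week 4 sham, 125 without the week 12 sham, 540 without week 4 cells replicate 2 and 1126 without week 12 cells replicate 1. Leaving out graft spots or the week 4 sham ended the calls of APOE, SFRP2, GPNMB, JCHAIN, MYOM2, CKM, ACAA2, SDHB, SDC2 and NOTCH2, and leaving out graft spots ended that of SDC1.

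Week 12 sections had more macrophage and inflammation RNA and less contractile and mitochondrial enzyme RNA in the host than week 1 sections (n = 4 each). The lectin CD209 was 76.2-fold higher, PDK4 8.88-fold, the complement gene C1QA of macrophages 5.0-fold and the chemokine CCL2 3.38-fold. CDH5 of endothelium was 2.06-fold and FABP4 2.62-fold higher. MYL3 was 11.4-fold lower (276 ± 184 against 2861 ± 696 CPM), MYL2 4.14-fold, CYC1 3.81-fold and HK1, the first enzyme of glycolysis, 2.80-fold. Contractile genes took 3.69% ± 2.09 of pig UMIs at week 12 and 8.55% ± 1.56 at week 1. Of 14 macrophage genes 10 rose (10 adjusted over the list alone; camera adjusted p = 1.64e-07, and adjusted p = 0.681 with an estimated correlation), and of 14 inflammation genes 8 rose (12 adjusted over the list alone; camera adjusted p = 4.55e-08, and adjusted p = 0.423 with an estimated correlation). Oxidative phosphorylation fell in 12 of 16 (16 adjusted over the list alone; camera adjusted p = 2.15e-09), contractile genes in 6 of 14 (11 adjusted over the list alone; camera adjusted p = 5.29e-06) and glycolysis in 9 of 13 (9 adjusted over the list alone; camera adjusted p = 5.18e-05), each with adjusted p = 0.681 with an estimated correlation. Pig MDK was at log2 0.70 ± 0.28 (adjusted p = 0.0873) and passed without the week 12 sham (0.89, adjusted p = 0.0482) and with total-count scaling (1.25, adjusted p = 0.0291). It was at 0.09 in muscle-rich spots (adjusted p = 0.864), -0.03 in muscle-poor spots (adjusted p = 0.978) and 0.14 with graft spots left out (adjusted p = 0.778). Without week 12 cells replicate 2 it was at 0.41 (adjusted p = 0.215), and with human-rich spots left out at 0.33 (adjusted p = 0.283). PTPRB, counted here in the midkine receptor list, was 2.50-fold higher. IFITM3, an interferon-induced antiviral gene, was 422-fold higher (272 ± 97.0 against 0.689 ± 0.392 CPM, log2 8.72 ± 0.47 SE, adjusted p = 5.98e-06) and the mitochondrial gene ATP8 28.0-fold. ATP8 shares its transcript with ATP6, and its UMIs were 0.0134% to 0.0588% of those of ATP6 in the sections of weeks 1 and 4 and 1.18% to 1.32% in those of week 12. Both steps were present in every week 12 section, sham and medium included. A change in the level of a shared transcript would leave that ratio as it was. The ratios thus argue against the ATP8 fold as a change in the level of that transcript. The IFITM3 fold is uncertain as a host change too, and a library batch that followed the weeks is not excluded. Such a batch would bear on every other contrast of week 12 with an earlier week too, those of human genes included. In all 1342 genes were higher and 1435 lower, against 3071 and 535 with total-count scaling. The total was 980 and 1822 without week 1 cells replicate 1 or 2, 1688 without week 12 cells replicate 1 and 4 in sham and medium sections alone, which ended the calls named here other than those of IFITM3, ATP8 and CD209. In muscle-poor spots 343 passed, without CCL2, CDH5, MYL3, MYL2, CYC1, HK1 and PTPRB. In muscle-rich spots 952 passed, without CCL2, CDH5, FABP4 and PTPRB. With graft spots left out 1314 passed, and with 1 mean per group 1239, without FABP4, MYL3 and MYL2. Leaving out graft spots also dropped week 4 cells replicate 2 and week 12 cells replicate 2.

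Of the host genes 182 were higher and 148 lower at week 4 than at week 1 (n = 4 each). PER1, a clock gene that glucocorticoids also induce, was 7.05-fold higher (178 ± 45.8 against 25.5 ± 3.14 CPM, log2 2.82 ± 0.27 SE, adjusted p = 0.00132), FKBP5, which binds the glucocorticoid receptor complex, 5.78-fold, and the transcription factors KLF15 and CEBPD 7.17-fold and 12.6-fold. CD163, a scavenger receptor of macrophages, was 5.64-fold higher. CD248 of stromal cells was 4.23-fold lower, CREB3L1, a regulator of collagen secretion, 3.68-fold, and the vessel growth factor ANGPT1 3.78-fold. Of 14 macrophage genes 1 rose (2 adjusted over the list alone; camera adjusted p = 0.0103), and of 10 activated fibroblast genes 1 fell (2 adjusted over the list alone; camera adjusted p = 0.0103), each with adjusted p = 0.759 with an estimated correlation. Pig MDK did not pass (log2 0.18 ± 0.28, adjusted p = 0.769), and ranged from -0.08 in muscle-poor spots (adjusted p = 0.952) to 0.54 in sham and medium sections alone (adjusted p = 0.708). With total-count scaling 225 genes were higher and 35 lower, and 2 passed in sham and medium sections alone, which ended each call named here but that of CEBPD. The total was 920 by DESeq2, 533 with no filter on low counts, 1227 in muscle-rich and 143 in muscle-poor spots, 178 with 1 mean per group and 1038 with human-rich spots left out. It was 92 without the week 1 medium, 46 and 86 without week 1 cells replicate 1 or 2, 688 without the week 4 sham, 22 without the week 4 medium, 88 and 80 without week 4 cells replicate 1 or 2, and 911 without week 12 cells replicate 2. Leaving out the week 4 medium ended the calls of CD163, CD248 and ANGPT1. Muscle-poor spots, 1 mean per group and leaving out graft spots each ended that of ANGPT1.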

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

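The tests of human reads, of muscle content and of glucocorticoid-induced genes were chosen only after the results they bear on were seen, as was the comparison of human-rich with human-poor spots, while the test of clock genes was chosen before. Of 147 groups of sections examined for a section that stood apart from the rest by Dixon's criterion, 16 had one. The criterion allows about 1 in 20 for independent draws from 1 distribution. These groups pool weeks or treatments and reuse the same sections, so that rate is not the chance rate for this count. Week 12 cells replicate 2, the section with the highest human share, stood apart from the other 5 cells sections in 5 pig genes: MDK at 204 CPM against 61.1 to 112, CD68 at 78.5 against 8.57 to 30.1, CD2 at 40.1 against 3.19 to 15.9, JCHAIN at 252 against 12.2 to 86.2 and MSR1 at 42.0 against 4.44 to 16.9. Among the 4 week 12 sections it stood apart in FABP4 (1865 against 761 to 848 CPM) and PTPRB (55.1 against 31.2 to 34.5). Pig MDK in human-rich over human-poor spots was at log2 2.34 in week 1 cells replicate 2 and at 1.05 to 1.52 in the other 5 cells sections. Week 1 cells replicate 1 was high among cells sections in COMP, at 303 against 18.0 to 85.8 CPM, and was the one week 1 section with MARCO, at 0.176 CPM against 0. Week 4 cells replicate 1 was low in FN1, at 219 against 511 to 556 CPM. Among week 1 sections the sham was high in CDH5, at 43.2 against 27.4 to 29.9 CPM, and the medium section low in MYL3, at 1827 against 3107 to 3343 CPM. Among week 4 sections the sham was low in PTX3, at 0.495 against 117 to 134 CPM, and in CEBPD, at 17.2 against 50.8 to 57.6 CPM, and the medium section was high in CD248, at 26.9 against 13.1 to 15.4 CPM.

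The effect of human-rich against human-poor spots differed between weeks for 23 of the named gene calls, by edgeR's interaction term. From week 1 to week 4 it gained 3.40 ± 0.66 for the apelin receptor APLNR (log2, SE, adjusted p = 0.000345), 2.92 ± 0.48 for FABP4, 2.76 ± 0.63 for CDH5, 2.75 ± 0.56 for LGALS3 and 2.54 ± 0.52 for SPP1, while LGR4 changed by -2.66 ± 0.45 and LOXL2 by -1.70 ± 0.41 (adjusted p = 0.0182). From week 1 to week 12 it gained 3.81 ± 0.87 for PDGFB, 3.58 ± 0.57 for CA4, 3.13 ± 0.72 for APLNR, 3.12 ± 0.49 for FABP4, 2.83 ± 0.51 for AQP1, 2.70 ± 0.60 for KDR, 2.57 ± 0.63 for CXCL9, 2.29 ± 0.53 for SPP1 and 1.81 ± 0.45 for SLA-DRB1 (adjusted p = 0.00746). The change was -3.22 for TNC, -3.18 for DKK3, -2.64 for COL1A1, -2.61 for CTHRC1, -2.29 for ACTC1, -2.26 for MYBPC3 and -1.91 for the midkine receptor SDC2 (adjusted p = 0.00448). Without week 1 cells replicate 1 the week 4 calls of APLNR, CDH5 and LOXL2 (adjusted p = 0.130, 0.0791 and 0.0525) and the week 12 calls of APLNR, PDGFB, SLA-DRB1, ACTC1 and MYBPC3 (0.215, 0.129, 0.117, 0.288 and 0.229) ended. Without week 1 cells replicate 2 the week 4 calls of CDH5, LGALS3, SPP1, LGR4 and LOXL2 (0.700, 0.988, 0.844, 0.0530 and 0.844) and the week 12 calls of KDR, CXCL9, SLA-DRB1, SPP1 and SDC2 (0.0705, 0.614, 0.137, 0.438 and 0.184) ended. Week 4 cells replicate 1 ended that of LGALS3 (0.278) and replicate 2 that of LOXL2 (0.0695). Without week 12 cells replicate 1 those of APLNR, PDGFB, CXCL9, SLA-DRB1, CTHRC1, ACTC1, SPP1 and SDC2 ended (0.21, 0.22, 0.613, 0.329, 0.518, 0.0813, 0.0832 and 0.283), and without replicate 2 those of COL1A1, MYBPC3 and SDC2 (0.0974, 0.0975 and 0.0771). The calls of FABP4, AQP1, CA4, TNC and DKK3 held without any 1 section.

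Pig immune genes lay higher in human-rich than in human-poor spots, where 69 of 79 members of the immune lists passed. Human reads counted on pig genes are argued against as the whole cause, since 65 of those 69 had a human gene of the same symbol and the upper quartile of human over pig UMIs in those spots was 0.145 (median 0.0181), with 3 genes holding more human than pig UMIs. The test of less muscle in those spots assumed that it would raise all other cell types alike, which was not shown. The median of T and NK cell genes, 2.33, exceeded that of endothelial genes by 1.81 on the log2 scale, with quartiles of 1.98 to 2.54 against 0.377 to 0.801. Without that assumption the gap cannot decide on muscle content, and a part for less muscle stays open. Against human-poor spots that were also poor in muscle the list medians were 1.20 for macrophage, 1.5 for T and NK cell, 1.10 for interferon response, 1.12 for antigen presentation, 1.93 for B and plasma cell and 0.73 for inflammation genes, with 9 of 13, 4 of 10, 12 of 19, 10 of 12, 3 of 6 and 5 of 12 members past the test, and 0 of 3 neutrophil genes passed. A host immune response to the human cells may be part of the pattern, as a hypothesis, and a local injury where cells were placed was not tested and stays open.

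Pig MDK also lay higher in human-rich spots. Taken by week, the excess of pig MDK UMIs per 100 human MDK UMIs was 16.8 ± 1.73 at week 1, 8.33 ± 0.35 at week 4 and 26.3 ± 2.56 at week 12 (counting error). The ratio of 1.56 between weeks 12 and 1 met the limit set for a fixed share of misassigned human reads. Week 4, which that ratio leaves out, lay below both beyond counting error, and week 1 pooled sections at 7.59 and 37.9. A second test, chosen after the first was seen, took the sections singly, and the excess ran from 6.38 ± 0.55 to 57.0 ± 4.10 per 100 (counting error), a ratio of 8.94 that argues against a fixed share of human reads as the whole cause. Against human-poor spots that were poor in muscle the log2 fold change was 0.96 ± 0.29 (adjusted p = 0.0567), from 1.43 ± 0.20 before, with the same 6 sections and a larger error, so that less muscle in human-rich spots stays open. A contribution of human reads that varies between sections also stays open, and no biological explanation was separated from these.

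At week 4 pig PER1, FKBP5, KLF15 and CEBPD, which glucocorticoids induce, were higher than at week 1, and glucocorticoid exposure may be the source. Of 12 other glucocorticoid-induced genes measured 4 passed over all genes (camera p = 0.0139 with an estimated correlation), but DDIT4 (log2 2.51, adjusted p = 0.00139), TSC22D3 (2.04, 0.00795) and KLF9 (1.34, 0.00661) had been seen before the list was written. Of the 9 not seen before, all 9 had a log2 fold change above 0 (median 0.91) and camera gave p = 6.22e-05, but p = 0.0656 with an estimated correlation, and DUSP1 alone passed over all genes (log2 1.49, adjusted p = 0.0252), short of the 3 genes asked for. The time of day at sampling also stays open, since 3 of 15 other clock genes passed, PER2 at 2.18, CRY1 at 1.62 and NR1D2 at -0.92, with a median absolute log2 fold change of 0.372. In sham and medium sections alone PER1 was at 2.65 (adjusted p = 0.397), FKBP5 at 1.79 (0.514), KLF15 at 2.80 (0.222), and CEBPD still passed, while handling and drugs, which the labels do not describe, would follow the week and cannot be told apart from it.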

How the results depend on the processing

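Leaving out human-rich spots, keeping sham and medium sections alone, thinning human counts, testing gene lists without week 12 cells replicate 2, and every alternative of the human-rich against human-poor comparison and of its change with the week were chosen after seeing the data. The cause of a moved count was not tested unless fewer sections, spots or counts entered. Among named genes the setting left the call the same in 2028 cases, ended it in 185, made it in 6 and made it with the sign turned in 1. Leaving out a section left it the same in 1762, ended it in 307, made it in 3 and turned the sign of a called gene in 0. The turned sign was that of pig NCL in human-rich spots, which was not called at first and was at log2 0.55 with total-count scaling. That move is close to the shift of the median of all genes under this scaling, so it is not particular to NCL. The human share of UMIs by section kept its ratio between 80.8 and 158 under the other ways of counting it, and the difference in graft spots lay between 30.0 and 76.2 points under other thresholds, all with p = 0.00216 (two-sided exact permutation test).

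With DESeq2 the counts of genes past the threshold were 6 for cells against medium, 594 for medium against sham, 3329 for cells against sham, 920 for week 4 against week 1, 1323 for graft against graft-free spots, 12 and 119 for the change of the human-rich effect to weeks 4 and 12, and 6, 2 and 80 within weeks 1, 4 and 12. Total-count scaling gave 462 for medium against sham, 6913 for cells against sham, 3354 for human genes between weeks 4 and 12, 5864 for graft against graft-free spots and 8023 for human-rich against human-poor spots. Without a filter on low counts there were 359 for medium against sham, 533 for week 4 against week 1, and 184, 9 and 584 within weeks 1, 4 and 12. In muscle-rich spots alone 5 genes passed for cells against medium, 685 for medium against sham, 352 for cells against sham, 952 for week 12 and 1227 for week 4 against week 1. Muscle-poor spots gave 6 for medium against sham, 416 for cells against sham, 343 for week 12 and 143 for week 4 against week 1. A model with 1 mean per group gave 1239 for week 12 and 178 for week 4. With graft spots left out, week 4 cells replicate 2 and week 12 cells replicate 2 were dropped, as they kept 1 and 4 spots. In the sections that remained 6 genes passed for cells against sham, 1314 for week 12 against week 1 and 124 within week 1. With human-rich spots left out 1794 passed for cells against sham, 1038 for week 4 against week 1, and 472, 13 and 75 within weeks 1, 4 and 12. Sham and medium sections alone, 2 a week, gave 4 for week 12 and 2 for week 4 against week 1. Spots at least 20% human gave 1150 human genes at week 4 against week 1 and 2451 host genes against graft-free spots. Human counts thinned to 126649 a section gave 469 at week 4 and 724 at week 12 against week 1 and 15 between weeks 4 and 12, where fewer genes could be tested. For human-rich spots 756 genes passed against muscle-poor human-poor spots, and 1469 with genes open to human reads left out.

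Gene lists passing with the preset correlation numbered 4 to 19 a comparison, and 0 passed with an estimated correlation in any. The limma test fry called 7 lists for medium against sham, 11 and 3 for human genes at week 4 against week 1 and week 12 against week 4, and 0 for cells against medium overall and within weeks, week 4 against week 1, graft against graft-free spots and the changes with the week. Its other counts stayed within 1.5 times.

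Leaving out each section in turn gave 0 to 0 genes for cells against medium, 2 to 420 for medium against sham, 30 to 2550 for cells against sham, 980 to 2852 for week 12 and 22 to 911 for week 4 against week 1. Within weeks 1, 4 and 12 it gave 0 to 237, 0 to 2 and 0 to 2642. Human genes ranged from 544 to 2390 at week 4 and 1154 to 3180 at week 12 against week 1, and from 397 to 3002 between weeks 4 and 12. Human-rich spots gave 3386 to 4632, and the changes with the week 7 to 45 and 75 to 212. The ratio of human shares ranged from 58.6 to 135 and the difference in graft spots from 61.4 to 79.5 points. A lone section left in a group was assumed to vary like the others. With the replicate number as a block human genes gave 1755, 2650 and 2133 calls for week 4 and week 12 against week 1 and week 12 against week 4. Same-numbered sections correlated at -0.082, 0.010 and 0.18 in the deviations of human genes and at 0.085, -0.091 and 0.39 in those of host genes. These were not above 0.1 in every pair, and the sections were treated as unpaired. With 2 sections a week the correlations cannot show that same-numbered sections are unrelated.

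Not run were graft against graft-free spots restricted to muscle-poor spots, where 1 section had enough spots, leaving out a section there, which leaves no residual degrees of freedom, and the planned change of graft-spot effects with the week, since only week 1 sections held both classes. Depth limits host genes most at week 12, with 7886726 ± 3612322 pig UMIs a section (SD, n = 4), and human genes at week 1, where genes with few UMIs allow only bounds.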

Other observations

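The comparison of human-rich with human-poor spots, the count of splits that keep the makeup of the groups, and the splits of the sections for medium against sham, cells against sham and week 12 against week 1, were chosen only after results were seen, while the splits for cells against medium, week 4 against week 1 and human-rich spots were chosen before. In the human cells hypoxia genes fell from week 4 to week 12, in 8 of 12 (8 adjusted over the list alone; camera adjusted p = 2.6e-07, and adjusted p = 0.489 with an estimated correlation). SLC2A1 went from 80.5 ± 9.11 to 27.4 ± 7.40 CPM, 3.02-fold lower, and LDHA from 777 ± 53.4 to 259 ± 6.20 CPM, 2.99-fold lower (SD, n = 2 each), both of which the glycolysis list holds too. With human counts thinned to the shallowest section the call of SLC2A1 ended (log2 -1.40, adjusted p = 0.412). Human fibroblast genes rose over the same weeks, in 7 of 11 (9 adjusted over the list alone; camera adjusted p = 0.000103, and adjusted p = 0.489 with an estimated correlation). MFAP5, a protein of elastic microfibrils, had 311 UMIs at week 12 and 3 at week 4, a ratio of 70.3 (counting interval 23.8 to 343), and the proteoglycan DCN was 4.14-fold higher (533 ± 498 against 129 ± 41.1 CPM). The DCN call ended without week 4 cells replicate 1 (adjusted p = 0.199) or 2 (0.0908) and without week 12 cells replicate 2 (0.182), where its log2 fold change was 0.48.

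In the host, genes of activated fibroblasts and cartilage rose in graft spots at week 1, against graft-free spots of the same 2 sections. ADAM12, a metalloprotease, was 8.17-fold higher (log2 3.03 ± 0.24 SE, adjusted p = 3.98e-32) and COL11A1, a fibrillar collagen, 8.51-fold. All 10 activated fibroblast genes rose (10 adjusted over the list alone; camera adjusted p = 2.3e-09) and all 6 cartilage and bone genes rose (6 adjusted over the list alone; camera adjusted p = 7.08e-09), each with adjusted p = 0.547 with an estimated correlation. Over all 6 cells sections B and plasma cell genes rose in human-rich spots in 5 of 8 (5 adjusted over the list alone; camera adjusted p = 0.00591, and adjusted p = 0.312 with an estimated correlation), with MZB1 6.48-fold higher (21.6 ± 12.3 against 3.96 ± 1.81 CPM, n = 6, higher in 6 of 6 sections). The chemokine CXCL14 was 14.2-fold higher in 6 of 6. At week 12 the host genes RGS1, a regulator of lymphocyte signalling, and NR4A3 and FOS, which stimulated cells switch on early, were 35.9-fold, 6.13-fold and 6.72-fold higher than at week 1 (n = 4 each). The FOS call ended in muscle-poor spots (log2 1.40, adjusted p = 0.162), with graft spots left out (2.30, adjusted p = 0.0699) and in sham and medium sections alone (3.22, adjusted p = 0.167), which also ended that of NR4A3 (2.84, adjusted p = 0.156).

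Other splits of the same sections were counted for each host comparison. For cells against medium the real split called 0 genes, a count that all 84 of 84 splits reach by definition, so that the splits tested nothing there, and the highest other called 3. For medium against sham 1 of 10 splits called as many as the real one, with 213 genes against 0 in the highest other, and 10 splits are too few for a share under 0.05. For cells against sham only the real split, 1 of 84, reached its count, with 2131 genes against 1 in the highest other. Among the splits that keep the weeks of both groups 1 of 27 did, the smallest share they can give. Chance is argued against there but not excluded. The comparison of week 12 with week 1 gave 1 of 35, with 2777 against 1, and that of week 4 with week 1 gave 1 of 35, with 330 against 0. Of those 35 only 12 keep 1 sham, 1 medium and 2 cells sections in each week, too few for a share under 0.05, and the highest other among them called 0 genes in either comparison. For human-rich spots the real labels called 4743 genes, and the highest of the other swaps within sections called 1078. Only 1 of 32 reached the real count, the smallest share these swaps can give, so chance is argued against but not excluded.

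Host counts of 2 kinds stepped between weeks 4 and 12. The 3 pig IFITM genes together stood at 1.04 ± 0.902 CPM at week 1, 0.925 ± 0.317 at week 4 and 272 ± 96.6 at week 12 (SD, n = 4 each), nearly all of it IFITM3 at week 12. While ATP8 was higher at week 12, the 12 other mitochondrial genes had a median log2 fold change of -0.56 there and none exceeded 1.83.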
